A study of Drosophila melanogaster with 3 samples.

How the data were processed

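Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of MYST5, the product of the gene CG1894, was carried out in S2 cells, a line of Drosophila melanogaster derived from embryos. Per the labels, 3 libraries were made, 1 from each of 2 independent rabbit antibodies against MYST5 and 1 from input chromatin, which is sheared DNA taken before any antibody is added. Each antibody was thus represented by 1 library, and the labels list no immunoprecipitation with a control antibody.

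The deposited data used here are 1 signal track for the whole series, with 1 value per position on the log2 scale, which the authors computed from all 3 libraries together. Per the submitters' processing notes, Bowtie 0.12.8 and genome build dm3 were used. The counting window, the normalization, the smoothing and any peak caller are not given in the sources used here. The track lists 4091516 positions on 2L, 2R, 3L, 3R, 4 and X, each an interval of 10 bp, spaced 25 bp apart. Of the positions on this grid, 85.1% were listed. The share was 74.9% on X and between 84.8% and 90.2% on the other chromosomes, so a density per Mb with a value and a density per Mb spanned differ on X. Heterochromatic sequences were not analysed here.

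What the values are was worked out from the values themselves. They behaved as a running median over the positions within 150 bp, 13 positions when none was missing. The value was exactly 0 at all 5293 positions with fewer than 5 listed positions in that window and at no other position, so these zeros were read as fill values and left out. Most recurring steps between values matched the increments of a negative binomial variance-stabilizing transform on the log2 scale for a change in the count of 1 library, and 146 of 1086 did not. With that transform, each unsmoothed value is the mean of the transformed counts of 2 libraries minus the transformed count of another library. At positions with full windows the 3 underlying whole-number counts could therefore be decoded. This succeeded for 303913 of 303917 distinct values at a tolerance of 2e-14, and for 0 of 20000 values shifted by a random amount. On a simulated track all distinct values decoded to the right counts, with 0 decoded to wrong ones.

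The 2 libraries averaged with a positive sign were read as the antibody libraries, and the subtracted one as the input, because the design holds 2 antibodies and 1 input. Which library came from which antibody is not known, so they are called antibody library A and antibody library B. The decoded counts are those the authors counted before transformation, at the position whose unsmoothed value was the median of the window. That position lies within 150 bp and need not be the one to which the counts are assigned. All counts per position or bin given below carry this limit. Neighbouring positions share reads, so counts at different positions are not independent, and the library totals are not known. The scaling factors in the transform put library A at 1.41 times and library B at 1.54 times the depth of the input. The median count per position was 28 in library A, 31 in library B and 20 in the input, with the 5th to 95th percentile at 8 to 83, 8 to 104 and 8 to 44. The lowest count at decoded positions was 1 in each antibody library, whereas the input held 0 at 191 positions, so a position appears to have been listed only where both antibody libraries had a count.

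The working unit was the 200-bp bin, with the mean of its listed values where at least 4 of its 8 positions had one, which left 533611 bins. Bins over the median plus 5 robust standard deviations (SD; 1.4826 times the median absolute deviation over the arms 2L, 2R, 3L, 3R and X) were called enriched, and enriched bins within 400 bp were merged into regions. For single libraries the same threshold was applied to the transformed antibody count minus the transformed input count in the 376350 bins with at least 4 decoded positions. The transform shrinks ratios where counts are low, so a log2 enrichment was not turned into a fold, and ratios over input were taken from decoded counts scaled by the factors of the transform. In a simulated track of 60000 bins with planted regions, 46 of 50 were recovered at 3-fold and 50 of 50 at each of 6-, 12- and 20-fold, with 1 region called outside them, but its threshold was 1.02, below the 2.27 of the data. The antibody counts in 2000 fully decoded bins of the arms, each under 3 robust SD in both libraries, were therefore multiplied as well. The share over the threshold of the data was 3.95% at 3-fold, 52.7% at 6-fold, 97.2% at 12-fold and 99.8% at 20-fold, so most sites of 3-fold enrichment would be missed. Whole bins were multiplied, so these shares do not cover sites narrower than a bin.

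Chromosomes were compared by differences of mean log2 values and ratios of region densities, with 95% intervals from 2000 resamples of 100-kb blocks. The design chosen before the data were examined had named a ratio of means, which does not apply to log values centred near 0, and a difference was used. The intervals show spread along the genome, not spread between replicates. No test across the 2 antibody libraries and 1 input was run, and no p-value is given. The spacing of regions was set against 1000 random placements of the same number of regions per chromosome, with the same merging. Simulated libraries without enrichment used the same local read density in all 3 libraries, averaged over 5000 bp, fragments covering 8 positions each, and the same transform and running median. Random thinning of decoded counts used 1 draw per bin and library, since the positions of a bin share reads. The 25 regions with the highest bins were named by a rule fixed before the data were examined. The regions that differ most between the antibody libraries, the groups of neighbouring regions and the 1-Mb windows were chosen after their values were seen. Alternatives covered the threshold, bin size, merging, minimum width, summary, background and each antibody library left out, and several more were added after the data had been seen. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

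Coordinates are those of dm3, counted from 1. The gene table at hand is on another assembly and coordinates were not converted, so no region was assigned to a gene. The share of regions at transcription start sites, the signal by gene part and the 16 gene lists chosen beforehand were therefore not analysed here.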

Results

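MYST5 belongs to the MYST family of acetyltransferases, whose best known fly member, MOF, acts on the male X chromosome in dosage compensation. The experiment mapped where MYST5 lies along the genome of S2 cells, a male-type Drosophila line, with 2 antibodies and 1 input library. The deposited track combined all 3 libraries into 1 log2 enrichment over input per position, a difference of variance-stabilized counts that lies closer to 0 than the log2 ratio of the counts where counts are low. Each antibody was represented by 1 library, so values below have no replicate error beyond the comparison of the 2 antibodies. The track filled 533611 bins of 200 bp. Over those on the 5 large arms the median log2 enrichment was -0.014 and the robust SD was 0.46.

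MYST5 enrichment over the threshold lay in short sites. A total of 949 regions lay over the threshold, a log2 enrichment of 2.27, and together they held 0.222% of the bins. The same distance below the median was reached by 1 region. Values could not fall as far as they could rise, since decoded positions held at least 1 count in each antibody library. The transform also shrinks ratios at low counts. Single positions ran from -2.51 to 5.17, so the number of regions below the median does not measure the noise above it. The median of the highest bins of the 949 regions was a log2 enrichment of 2.69, and 19 regions exceeded a log2 enrichment of 4. Of the 949 regions, 753 (79.3%) were a single bin, and the longest spanned 1400 bp. The number depended on the threshold: 4360 regions passed at 3 robust SD, where 833 lay equally far below the median, and 2 passed at 10 robust SD. Bins of 500 bp gave 410 regions, and 188 regions had at least 2 adjacent bins over the threshold. Library A alone, without library B, gave 343 regions, and library B alone gave 860.

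**Figure D1:**
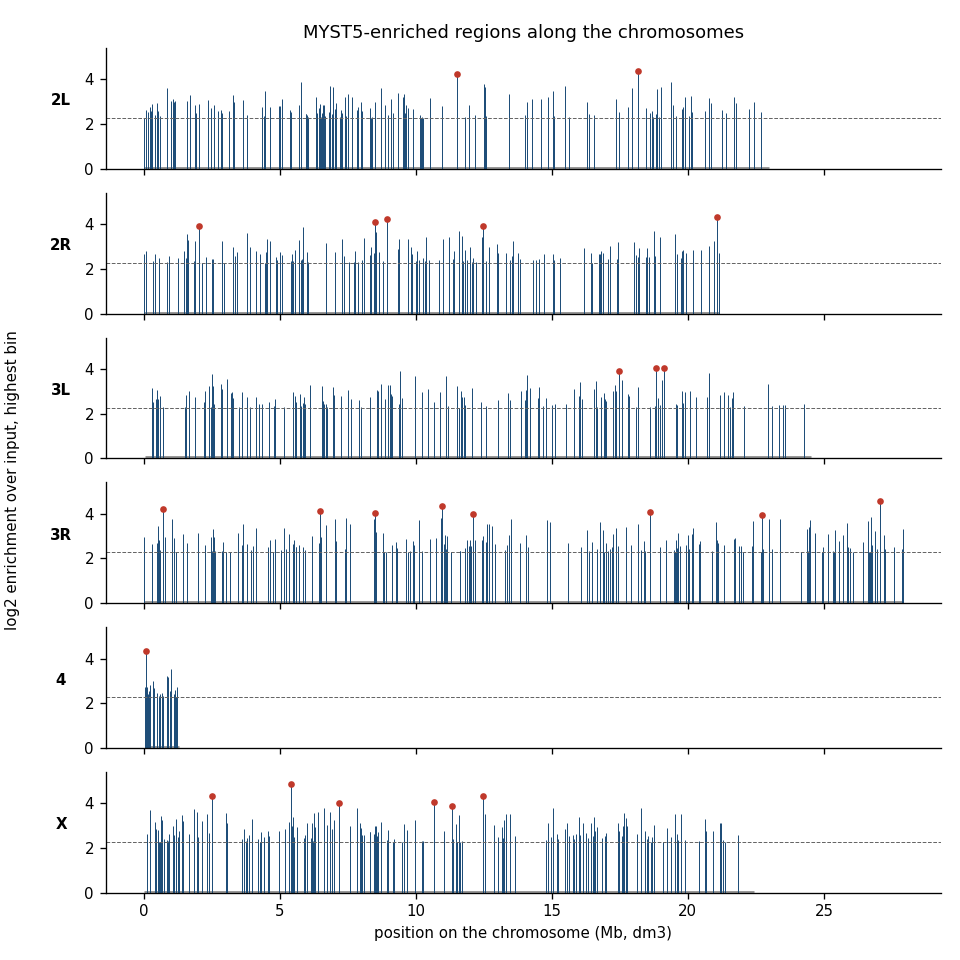
Each vertical line is 1 of the 949 enriched regions, drawn at its dm3 position in Mb on the x axis with the log2 enrichment of its highest bin on the y axis. The dashed line is the threshold of 2.27, the grey bar is the span of the track and red points are the 25 highest regions, which lie on all 6 chromosomes analysed.

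The highest region was X:5418601-5419000, with a log2 enrichment of 4.86. On X, 5 further regions ranked among the 25 highest. These were X:2511401-2511800 at a log2 enrichment of 4.34, X:12477201-12477400 at 4.32, X:10662201-10662600 at 4.04, X:7180201-7181000 at 4.02 and X:11348401-11348600 at 3.90. Arm 3R held 8 of the 25, led by 3R:27045201-27045600 at 4.57 and 3R:10957601-10958000 at 4.33. The other 3R regions were 3R:731601-732000 at 4.19, 3R:6500801-6501200 at 4.14, 3R:18619801-18620000 at 4.06, 3R:8517201-8517600 at 4.02, 3R:12086201-12086800 at 3.97 and 3R:22707201-22707400 at 3.95. Arm 2R held 5, namely 2R:21070401-21070800 at 4.34, 2R:8930801-8931000 at 4.23, 2R:8499601-8500200 at 4.08, 2R:12459201-12459400 at 3.92 and 2R:2038601-2039000 at 3.91. Arm 3L held 3L:18841601-18841800 at 4.06, 3L:19133401-19133800 at 4.04 and 3L:17468001-17468200 at 3.92. Arm 2L held 2L:18152401-18152800 at 4.36 and 2L:11517001-11517400 at 4.23. Chromosome 4 held 1, the region 4:89201-89800 at 4.32.

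Counts could be decoded at 22 of these 25 regions, and all 22 lay over 5 robust SD in each antibody library taken alone. At 3R:27045201-27045600 the mean count per position in the highest bin was 1380 in library A and 2089 in library B against 41.8 in the input. At the chromosome 4 region the counts were 1157, 2665 and 54.0. Of the 22 regions, 13 were more enriched in library B and 9 in library A.

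Over all regions, both antibody libraries rose above the input, library B more than library A. In the 897 regions with decoded counts the median count at the highest bin was 281 in library A, 498 in library B and 31.9 in the input. Over all decoded bins the medians were 28.6, 31.0 and 19.6, so the regions held 9.82 times the usual count in library A, 16.0 times in library B and 1.62 times in the input. The median log2 enrichment of the regions was 2.45 in library A and 3.11 in library B, and the median ratio of counts over input, scaled for depth, was 6.58 and 10.5. Enrichment was above 0 in both libraries in all 897 regions, over 3 robust SD in both in 790 (88.1%) and over 5 robust SD in both in 208 (23.2%). Library B was the higher one in 641 regions and library A in 256. Because regions were chosen by the mean of both libraries, these counts describe the regions and do not test the libraries independently.

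**Figure D2:**
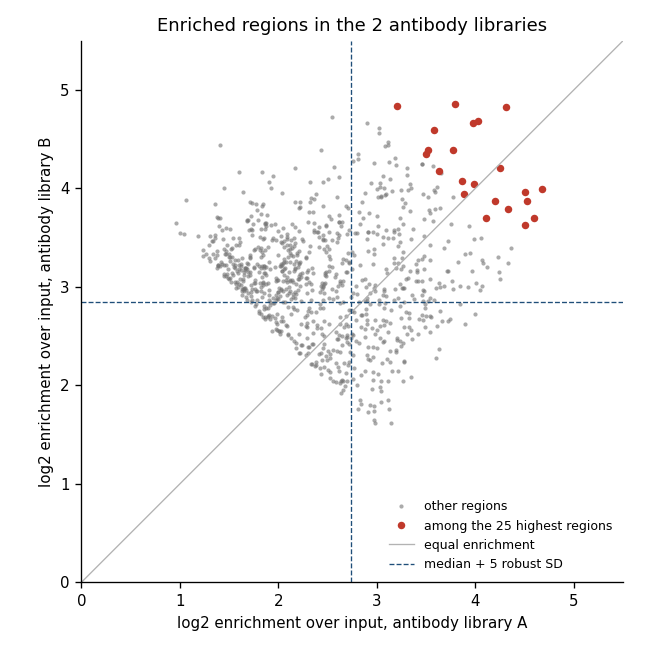
Each point is 1 of the 897 regions with decoded counts, with the log2 enrichment over input at its highest bin in antibody library A on the x axis and in antibody library B on the y axis. Dashed lines are the threshold of each library (median plus 5 robust SD), and the slanting lower left edge comes from choosing regions by the mean of both. All points lie above 0 on both axes, and more of them lie above the line of equal enrichment (641) than below it (256).

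Called separately, library A had 413 enriched bins and library B had 1016, of which 246 were shared. These made up 59.6% of the library A bins (95% Wilson interval 54.8% to 64.2%, for counting error only) and 24.2% of the library B bins. Independent lists of these sizes would share 1.11 bins, a figure that leaves out the effect of the shared input. At the lower level of 3 robust SD, 403 of the 413 library A bins were reached in library B, and 643 of the 1016 library B bins in library A. Across the 376350 decoded bins, which are not independent replicates, Pearson's r between the enrichments of libraries A and B was 0.36 and Spearman's rho was 0.29. Their covariance was 0.133, against 0.0316 in simulated libraries without enrichment and with the input shared between them, which had a smaller variance (0.0594 against 0.329 in library A) and r of 0.55. In the simulation r was 0.63 before the running median was applied. A shared input alone gives some correlation without any enrichment. The simulated variance lay below that of the data in library B as well (0.0565 against 0.404). The simulated r and covariance are therefore not a reference for the observed ones. Neither r nor the covariance is read as a measure of reproducibility here.

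Over the regions the median difference of library A minus library B was -0.74. Region 2L:21757401-21757600 had a log2 enrichment of 4.44 in library B and 1.41 in library A, with mean counts of 1560 and 167 over an input of 41.3. Region 2R:1250601-1250800 stood at 3.89 in library B and 1.06 in library A. The largest difference in the other direction, at X:21293001-21293200, was 3.14 in library A against 1.62 in library B, about as far from that median as the first of these. These 3 regions were chosen after their values were seen.

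X was compared with the autosomal arms because the related enzyme MOF acts on X. Mean log2 enrichment was 0.081 on X and -0.0063 on 2L, 2R, 3L and 3R together, a difference of 0.087 (95% interval 0.076 to 0.098 over 100-kb blocks). The difference lay in the bulk of the bins, with medians of 0.054 on X and -0.026 on the autosomal arms. Enriched regions numbered 196 on X, or 10.9 per Mb with a value, against 8.32 per Mb on the autosomal arms, a ratio of 1.31 (1.10 to 1.54). That ratio depended on how it was measured. It was 1.16 (0.97 to 1.36) per block spanned in place of per Mb with a value, and it turned to 0.86 (0.71 to 1.03) when each chromosome was scaled by its own median and robust SD. It was higher, at 1.59 (1.46 to 1.74), with the threshold at 3 robust SD and 1.84 (1.56 to 2.15) in decoded bins alone, where it was 2.25 (1.77 to 2.86) without library B and 1.73 (1.44 to 2.06) without library A. The median input count on X was 0.770 times that of the autosomal arms. Among the autosomal arms, region density ran from 7.71 per Mb on 3L to 9.03 per Mb on 2R.

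**Figure D3:**
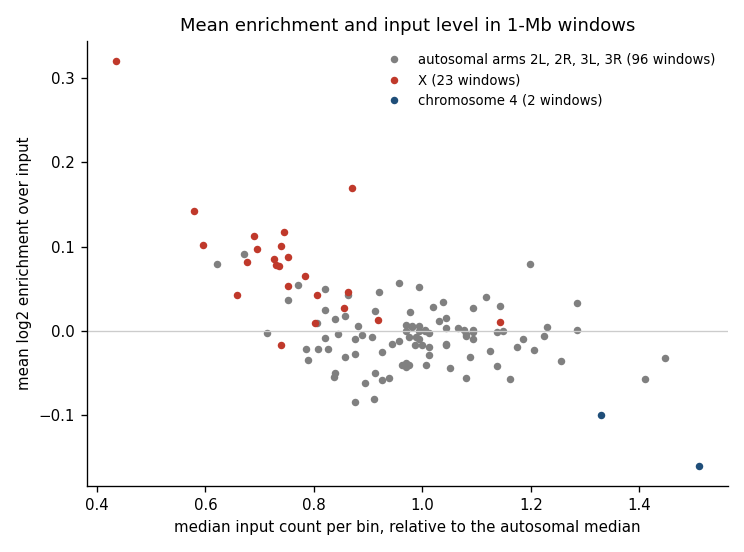
Each point is a 1-Mb window with at least 500 decoded bins, with its median input count relative to the autosomal median on the x axis and its mean log2 enrichment on the y axis. The 23 windows on X lie between -0.016 and 0.32 and mostly at lower input, the 96 autosomal windows lie between -0.084 and 0.091, and the 2 windows on chromosome 4 lie at -0.16 and -0.10.

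Chromosome 4, the small and largely heterochromatic autosome, combined a low average with many enriched sites. Its mean log2 enrichment was -0.11, lower than that of the arms by a difference of -0.12 (-0.15 to -0.090). It held 24 regions in 1.10 Mb with a value, or 21.7 per Mb, 2.48 times the density of the arms (1.73 to 3.35). In decoded bins alone the ratio was 2.19 (1.58 to 2.95) with both libraries, 1.21 (0.46 to 2.06) without library B and 3.27 (2.28 to 4.42) without library A. At 3 robust SD the ratio was 1.36 (1.16 to 1.61). The median input count on chromosome 4 was 1.39 times that of the autosomal arms.

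On the whole track, regions stood slightly closer together than random placement would put them. Of the 949 regions, 17.7% lay within 10 kb of another, against a mean of 14.5% in 1000 random placements (range 10.4% to 19.5%), and 15 placements reached the observed share. The placements were even over bins with a value and did not follow local input. Region density over autosomal blocks rose with local input, by 6.65 regions per Mb per log2 unit (5.05 to 8.33), so the placements do not separate the spacing from that trend. Single regions made up 781 of the 949, and 7 groups held at least 3 regions. The largest group was 4 regions in 3R:25683201-25694800, and the group with the highest bin was 3 regions in 3L:17459001-17469400. At 3 robust SD, with more regions, 58.7% had such a neighbour against a random mean of 51.1% and a highest of 53.7%, so 0 of 1000 placements reached that share. In decoded bins alone the excess was smaller, with 18.1% against 16.1% at random, a share that 110 of 1000 placements reached. It was not seen without library B, where 4.66% of 343 regions had a neighbour within 10 kb against 6.16% at random.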

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

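The tests in this part were all chosen or changed after the results they bear on had been seen.

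The excess of enriched bins on chromosome 4 differed between the antibody libraries. Relative to the arms, chromosome 4 had 1.62 times as many enriched bins in library A (0.54 to 3.01, from 8 bins) and 3.18 times as many in library B (2.14 to 4.45, from 38 bins). The ratio of these was 1.97 (1.22 to 5.30 over 100-kb blocks, 13 of them on chromosome 4). Deeper coverage of chromosome 4 was weighed by thinning its counts at random to the depth of the arms. Both libraries fell, to 1.41 and 2.84 times the arms, and the ratio was then 1.99 (1.14 to 6.68), a change by a factor of 1.01 (0.756 to 1.84 over blocks and draws). Depth would have to lower it by a factor of 0.713 to account for most of it on the log scale, which lies just outside that interval, so the test argues against depth as the main cause by a narrow margin and rests on 8 bins in library A. A second protein recognised by 1 antibody is a candidate explanation that stays open and was not tested, and the design holds no control antibody and no cells lacking MYST5.

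The excess of enriched bins on X also differed between the libraries, being 2.36-fold in library A (1.81 to 3.07) and 1.78-fold in library B (1.46 to 2.16), a ratio of library B to library A of 0.75 (0.58 to 0.97). Both intervals show spread along the genome of 1 library per antibody.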

How the results depend on the processing

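Settings added after the data had been seen were the scaling of each chromosome by its own spread, the density per block spanned, the restrictions to decoded bins, full windows, complete bins or an input count of at least 10, the lower threshold for chromosome 4 and for the antibody libraries, and leaving out an antibody library for results other than the number of regions. Of 43 alternative values over all results, 31 kept their direction and their side of the threshold or stayed near the reported value, 5 counts moved by over 1.5 times, 5 lost their side of the threshold and 2 reversed. The number of regions, 949, moved to 2 at 10 robust SD, 4360 at 3 robust SD, 410 with 500-bp bins and 188 when at least 2 adjacent bins were required, and ranged from 343 to 860 when 1 antibody library was left out. The other settings gave 940 to 1115 regions. The difference in mean between X and the autosomal arms was 0.0069 once each arm's own median was subtracted, which removes a shift of all bins by construction. In decoded bins the difference was 0.11 with both antibody libraries, 0.092 without library B and 0.13 without library A. The X density ratio, 1.31, was 1.15 with arm medians subtracted, 1.16 per block spanned and 0.86 with each arm's own median and robust SD. The last of these reversed, with an interval that included 1 (0.71 to 1.03). Its cause was not tested beyond the wider spread of values on X that the scaling removes. In decoded bins the robust SD was 0.477 on X and 0.435 on the autosomal arms, and thinning the autosomal counts to the depth of X gave 0.445. At 3 robust SD the X density ratio was 1.59. In decoded bins alone the ratio was 1.84, and with 1 antibody library left out it was 1.73 to 2.25, and these values are not directly comparable with 1.31 because a smaller part of X than of the autosomes could be decoded. For chromosome 4 the mean difference stayed between -0.17 and -0.12, and in decoded bins with both antibody libraries it was -0.15. The density ratio ran from 1.21 to 3.27 with 1 antibody library left out, against 2.19 in decoded bins with both. The 1.21, without library B, had an interval that included 1. At 3 robust SD the density ratio was 1.36. The share of regions within 10 kb of another was 4.66% without library B, below the random mean of 6.16%, and 19.4% without library A. In decoded bins it was 18.1%, which 110 of 1000 placements reached, and the cause was not tested. It was 58.7% at 3 robust SD and 20.1% without merging, each reached by 0 of 1000 placements, and 16.3% with merging within 1000 bp, reached by 31. At 10 robust SD too few regions were left for density or spacing. Alternatives that need gene positions were not run, for lack of a dm3 annotation. No paired analysis was possible because each antibody had 1 library and the single input library served both.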

Other observations

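The tests in this part were chosen or changed after the results they bear on had been seen.

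The decoded input counts varied along the genome, and the data at hand do not separate DNA copy number from mappability, base composition or the rule by which positions were listed. The median input count was 0.770 times the autosomal level on X and 1.39 times on chromosome 4, and it varied within arms. Among 1-Mb windows of the autosomal arms with at least 500 decoded bins it ranged from 0.62 times the autosomal median at 2R:16000001-17000000 to 1.45 times at 2L:8000001-9000000, and on X it was lowest at X:1-1000000, at 0.43 times. At X:13000001-14000000 it stood at 1.14 times, above the rest of X. By number of enriched regions, not per Mb with a value, the highest windows were 4:1-1000000 with 19, 2L:6000001-7000000 with 17 and 2L:7000001-8000000 with 16, while X:1-1000000 held 15 with a value in only 54.4% of its bins.

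The shift of X toward higher enrichment was set against 3 technical explanations. Depth was tested at decoded positions, where X minus autosomes was 0.11 in place of 0.087 and enriched bins numbered 24.7 per Mb on X against 13.3. Random thinning of autosomal counts to the depth of X gave a share of 0.043 of this difference in mean (0.040 to 0.046 over 5 draws) and -0.056 of the excess density of enriched bins (-0.074 to -0.038). At decoded positions this argues against counting depth as the cause of either. Windows were full at 55.0% of the listed positions on X, against 72.5% to 78.2% on the autosomal arms, so much of X lay outside the test. Thinning acted on positions already listed and does not test the rule by which they were listed. Among the 61 X blocks of 100 kb with an autosome-like input count, a share of 0.23 of the mean difference was gone (0.049 to 0.40), leaving 0.067 (0.050 to 0.084). Among the 45 X blocks with an autosome-like share of listed positions 0.13 was gone (-0.081 to 0.35). Low local input or missing positions, each taken alone, may thus account for part of the mean difference and not for most of it. The 2 were not matched together, so their joint share is not known. For the density the shares gone in these 2 comparisons were 0.11 (-1.19 to 1.33) and -0.099 (-2.09 to 1.32), too wide to decide. Within X, mean enrichment fell as local input rose (slope -0.057 per log2 unit of input, -0.083 to -0.034), whereas over autosomal blocks together it rose (0.027, 0.016 to 0.037), on 2L, 3L and 3R but not on 2R (-0.0050, -0.028 to 0.019). Without the first Mb of X the mean difference was 0.079 (0.069 to 0.089). The values decoded with 1 factor per library on all chromosomes, and such a factor shifts X and autosomes alike except through the transform at low counts. Unscaled median counts on X were 24 in library A, 26.4 in library B and 15.5 in the input. On the autosomal arms they were 29.25, 31.5 and 20.1. The input was thus relatively lower on X than either antibody library, which argues against the authors' scaling as the main cause in decoded bins. Base composition stays open for lack of a genome sequence of this build, and a hypothesis of weak MYST5 binding spread over X was not tested.

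The enriched regions themselves were set against technical explanations of 2 kinds. A chance dip of the input would give high ratios where the input is low. The median input count at the regions was 1.62 times that of all bins, and 7 of 897 regions had an input count under 5. The transform shrinks ratios at low counts, so at the same ratio a bin with a high input passes the threshold more easily. Few regions thus lay at low input counts, but the raised input does not by itself argue against dips of the input. A signal of 1 antibody alone would leave the other library near its background. Since regions were chosen by the mean of both libraries, this was tested on bins called in 1 library, at input counts of at least the median. The other library lay at or below 1 robust SD in 0.0% of 316 library A bins (up to 1.20%). For the 863 library B bins the share was 1.04% (0.55% to 1.97%). Among all bins at such input counts the shares were 85.9% and 88.4%. These intervals are for counting error only and take bins as independent, although neighbouring bins share reads. Of the library B bins, 62.0% exceeded 3 robust SD in library A and the rest did not, so a part carried mainly by library B stays open. Also open is whether some of these sites are ones that many antibodies enrich, such as open chromatin. The raised input at the regions (1.62 times) is a feature such sites could share, but the threshold also favours bins with a high input. No control antibody was there to test whether the regions hold such sites.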
